A study of Mus musculus with 21 samples.

How the data were processed

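Total RNA from mouse splenic CD8+ T cells and from haematopoietic stem cells (HSCs) was sequenced by the authors. Per the labels, RNA came from a column kit with removal of genomic DNA, and stranded libraries were made after depletion of ribosomal RNA. A protocol field of the labels writes HECs in place of HSCs; the cell type label, HSC, is used throughout. The 21 samples fall into 9 groups by cell type, Rnps1 genotype and Tnf genotype, taken from the genotype labels. The 11 deposited tables used here hold results of comparisons between genotypes. The file headers call the replicates independent cultures; no sort gate, animal or pairing is given in the sources used here.

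In the deposited gene table, the authors give each gene's expression per genotype in FPKM, a measure of fragments scaled by transcript length and library size, with a p-value and a q-value. Per the file headers, the q-values came from a generalized linear model. The submitters' processing notes name cutadapt 1.9, TopHat2 2.0.10, Cufflinks 2.1.1, Cuffdiff, R 3.5.3 and the mm10 build, without a role or order. The table lists only genes the authors called significant, so a gene that is absent from it has no value here. The deposited enrichment sheets of the authors give fold enrichment as a ratio of 2 shares of genes, a P value and a Benjamini-adjusted p-value per term. In the deposited isoform tables the authors give isoform fractions, the share of a gene's expression carried by 1 isoform, for isoforms with a premature stop codon, and gene levels in FPKM. In the 6 deposited splicing tables the authors give counts of junction reads, inclusion shares as fractions, a log2 fold change of the event region between genotypes, a p-value and a false discovery rate. The splicing tables hold events at P under 0.05 per the file headers, and the number of events tested is not given in the sources used here, nor are the splicing software and the meaning of a star that some event types carry. Starred and plain types were counted together.

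The direction of a splicing event is the sign of the authors' log2 fold change, second genotype over first. Inclusion shares are the authors' values over the pooled reads of a genotype. For introns and exons the deposited share equals the reads of both inclusion junctions over these reads plus 2 times the exclusion junction reads; for alternative splice sites the exclusion reads enter once. Inclusion reads were recovered from the share and the exclusion reads, and every recovered count lay within 0.01 of a whole number. Exact (Clopper-Pearson) 95% intervals of a share cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Exclusion reads per library were summed over listed events as the only measure of depth in the tables. For the other 55 columns of reads per library the names did not tie a column to a sample, and these columns were not used. Models on reads per library and comparisons without single libraries were therefore not run. In the HSC table of mutant against wild type, 3 columns of exclusion reads stood beside 2 listed mutant samples, so mutant libraries had no depth there and the pooled-read test was not run for that table.

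Of the 559 entries in the deposited HSC table of Tnf loss, 157 were equal in every cell to entries of the corresponding CD8 T cell table and were left out. For 4 genes of the deposited splicing tables whose symbol had been turned into a date by a spreadsheet, the symbol was taken from the gene identifier. Gene symbols were matched to lists by symbol or by a sole other name. Event positions were set against GENCODE M21, which holds 1685 of the 1686 gene identifiers of the splicing tables, to name introns, exons and untranslated regions.

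All tests were two-sided. The split of genes or events into higher and lower was compared with equal shares by exact binomial tests, with Benjamini-Hochberg adjustment over the 4 event types of a table. Event types were compared between tables, and lists with other genes, by Fisher's exact tests. Events were matched between tables by gene, type and coordinates over 15 pairs of tables, and the share with the same direction was tested by an exact binomial test. That test takes equal shares as chance and ignores that each table is split unevenly, so its p-values are not reported. In its place, chosen after the results had been seen, directions at shared introns and at shared exons were compared by Fisher's exact tests, adjusted over the 22 tests with at least 5 shared events, and set beside the share that the splits of both tables would give if they were independent. Because some pairs share a group of samples, the share expected without any difference was simulated for them with 2000000 draws. In these draws the shared group had the same values in both tables. Pooled reads of each event were compared by Fisher's exact test. That test measures differences between pooled libraries and not between conditions, because replicate columns differed by more than counting error. Genes and events are not independent replicates, so binomial p-values describe the lists and not the mice. The pooled-read test was tested on simulated data of the size of the CD8 T cell table of 1113 events, in which 200 events were changed. It called 33 of 67 events with odds changed 1.5 times, 48 of 67 at 2 times and 62 of 66 at 4 times, all in the right direction. It called 10 of 913 unchanged events, and a binomial test of direction passed p of 0.05 in 39 of 1000 simulated tables without a difference. These simulations held no spread between replicates and no dependence between events, so their rates do not carry over to the real libraries. Calculations used Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, and plots matplotlib 3.10.9.

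The tests, the 16 gene lists, the rule for named genes and most alternative settings were chosen before the data were examined. The lists cover TNF and TNF receptor signalling, interferon response, cytotoxic effectors, naive and memory state, T cell receptor activation and checkpoints, T cell identity, cell cycle, p53 and apoptosis, the exon junction complex with RNA surveillance, splicing factors, HSCs and progenitors, and markers of myeloid cells, B cells, erythroid cells, megakaryocytes and platelets, and CD4 and NK cells. Another 4 lists, for pancreatic acinar cells, splenic macrophages, neutrophils, and basophils with mast cells, were written after the gene table had been seen. Named genes are Rnps1 and Tnf, the 10 genes with the largest change in each direction that had at least 1 FPKM in a genotype and a value above 0 in both, and up to 6 listed members of each fixed list, smallest adjusted p first. Named events and isoforms are, per table, the 5 with the largest change in each direction at an authors' false discovery rate under 0.05 and at least 20 reads in each group, Rnps1 and Tnf where listed, and up to 6 members of 6 lists, smallest p first. A gene named outside this rule is said to be so, and 3 items that meet it are not reported here.

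Alternative settings chosen at that time were a stricter threshold on q-values, Benjamini values and false discovery rates, a minimum of 1 FPKM, a minimum log2 change of 1, a pseudocount of 1 FPKM, removal of genes listed at 0, a minimum of 20 reads, a minimum change in inclusion share of 0.1, a minimum isoform fraction change of 0.2, 1 event per gene and overlapping coordinates. Settings added after seeing the data left out marker genes or genes of the gene table, took direction from the inclusion share, kept the repeated entries and counted repeated terms.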

Results

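Rnps1 encodes an RNA-binding protein that works with the exon junction complex in splicing, and Tnf encodes the inflammatory cytokine tumour necrosis factor. The series compared mice carrying the F181I allele of Rnps1, called ub in the labels, with wild-type mice, and asked how the loss of Tnf changes transcripts of the mutant. Sequencing covered 13 samples of splenic CD8+ T cells and 8 samples of HSCs. The CD8 T cell groups held 2 wild-type samples, 2 ub/ub samples, and in a separate set 3 ub/ub samples with intact Tnf, 3 +/ub samples without Tnf and 3 ub/ub samples without Tnf. The HSC groups held 3 wild-type samples, 2 ub/ub samples with intact Tnf, 2 +/ub samples without Tnf and 1 ub/ub sample without Tnf. Library totals are not given in the sources used here. Exclusion junction reads of listed events summed to between 668899 and 901831 per library for CD8 T cells of ub/ub and wild-type mice, and to between 172501 and 316707 for the comparison of Tnf loss in CD8 T cells. In HSCs these sums lay between 139588 and 154893 per wild-type library and between 171049 and 182066 in the comparison of Tnf loss. Each comparison sums over its own events, 1113 and 559 for the 2 CD8 T cell comparisons, so the sums do not compare depth between them. Medians per event and library ran from 143 to 216 reads in the first of these and from 60 to 133 in the second.

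The first comparison asked which genes differ in expression between ub/ub and wild-type CD8 T cells. Erythroid genes were higher in the mutant, genes of the B cell list and of digestive enzymes were lower, and genes of tissue macrophages were among the largest decreases. The transferrin receptor gene Tfrc went from 33.1 FPKM in wild type to 328 FPKM in the mutant, and the carbonic anhydrase genes Car1 from 9.80 to 77.7 FPKM and Car2 from 57.9 to 263 FPKM. The invariant chain gene Cd74 went from 872 to 207 FPKM and the MHC class II gene H2-Eb1 from 239 to 58.8 FPKM. FPKM values are the authors' values per genotype in the deposited gene table and carry no error; folds and log2 changes were computed from them. Of the 267 listed genes, 90 were higher and 177 were lower in the mutant, or 66.3% lower (two-sided exact binomial p = 1.1e-07). Of these, 17 genes were listed at 0 in wild type and 3 at 0 in the mutant, and no fold was computed for them. The lowest q-value in the authors' deposited table was 0.0142, which 198 genes shared, and the highest was 0.0499.

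All 12 listed members of the erythroid list of 30 genes were higher in the mutant (two-sided Fisher's exact test against the other listed genes, adjusted p = 5.14e-06). Beyond the genes above, the membrane skeleton gene Epb42 was 7.30-fold higher, Ermap 6.62-fold higher and Gata1, a master regulator of the erythroid lineage, 6.15-fold higher. All 17 listed members of the B cell list of 33 genes were lower (Fisher's exact test, adjusted p = 0.0019). Among them were Fcmr (log2 change of -2.30), the transcription factor gene Spib (-2.28), Ly6d (-2.18) and Fcrla (-2.11). Immunoglobulin variable genes, looked at after their values were seen, went both ways: of 8 listed, 5 were higher in the mutant, by 7.49-fold (Igkv8-30) to 10.2-fold (Ighv3-8), and 3 were lower. Of the 47 genes on the cell cycle list 4 were listed, all higher (Fisher's exact test, adjusted p = 0.0165). The proliferation marker Mki67 went from 10.8 to 57.2 FPKM and Rrm2, a subunit of ribonucleotide reductase, from 14.8 to 60.1 FPKM. Ccnb1 went from 3.17 to 15.6 FPKM and Cenpf from 1.55 to 5.40 FPKM. These cell cycle genes rose in the same libraries as the erythroid genes. The myeloid list held 12 listed genes of which 10 were lower and 2, the calprotectin genes S100a8 and S100a9, were higher, a split that did not differ from that of the other genes (Fisher's exact test, adjusted p = 0.348). S100a8 went from 217 to 1039 FPKM, while Adgre1, which encodes the macrophage antigen F4/80, went from 7.69 to 0.481 FPKM and Lyz1 was 13.5-fold lower. Of the HSC and progenitor list, Tal1 was 8.64-fold higher and the receptor gene Flt3 was 4.34-fold lower. Of the megakaryocyte and platelet list, Nfe2 was 5.12-fold higher, and of the interferon list, Ifi204 went from 3.03 to 0.325 FPKM.

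The listed members of T cell lists numbered 0: none of the genes in the lists for T cell identity, cytotoxic effectors, naive and memory state, or T cell receptor activation and checkpoints appeared in the gene table. The same held for TNF and TNF receptor signalling, p53 and apoptosis, the exon junction complex and RNA surveillance, splicing factors, and CD4 and NK cell markers. Rnps1 and Tnf were not in the table either. Because only genes called significant are listed, values for these genes were not analysed here and no limit can be set on their change.

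Among genes with at least 1 FPKM in a genotype, the largest decreases were in Ace (7.58 to 0.238 FPKM, log2 change of -4.99), which encodes angiotensin-converting enzyme, and in Adgre4 (-4.53) and Vcam1 (-4.49). The 3 chains of complement C1q followed, with C1qc at -4.31 and C1qa and C1qb at -4.27, beside Cd300e (-4.28), Adamdec1 (-4.26), Timd4 (-4.25) and Mertk (-4.21), a receptor for the uptake of dying cells. The largest increases were in Ankrd36 (0.00331 to 1.60 FPKM), Gm5483 (0.246 to 47.5 FPKM) and the stefin gene Stfa2l1 (0.648 to 44.6 FPKM). Lipg, an endothelial lipase gene, went from 0.0471 to 2.45 FPKM, Trib3 from 0.371 to 10.6 FPKM and Asns, which encodes asparagine synthetase, from 1.07 to 24.7 FPKM. Of a list of pancreatic acinar genes written after the table had been seen, 12 of 22 were listed, all lower, with a median log2 change of -2.82, and of a list of splenic macrophage genes written at the same time 16 of 19, all lower, with a median of -3.81. Reep6 (4.53), Olfm4 (4.27), Gm23731 (4.18) and Tmem56 (4.02) completed the 10 largest log2 changes upwards.

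**Figure D1:**
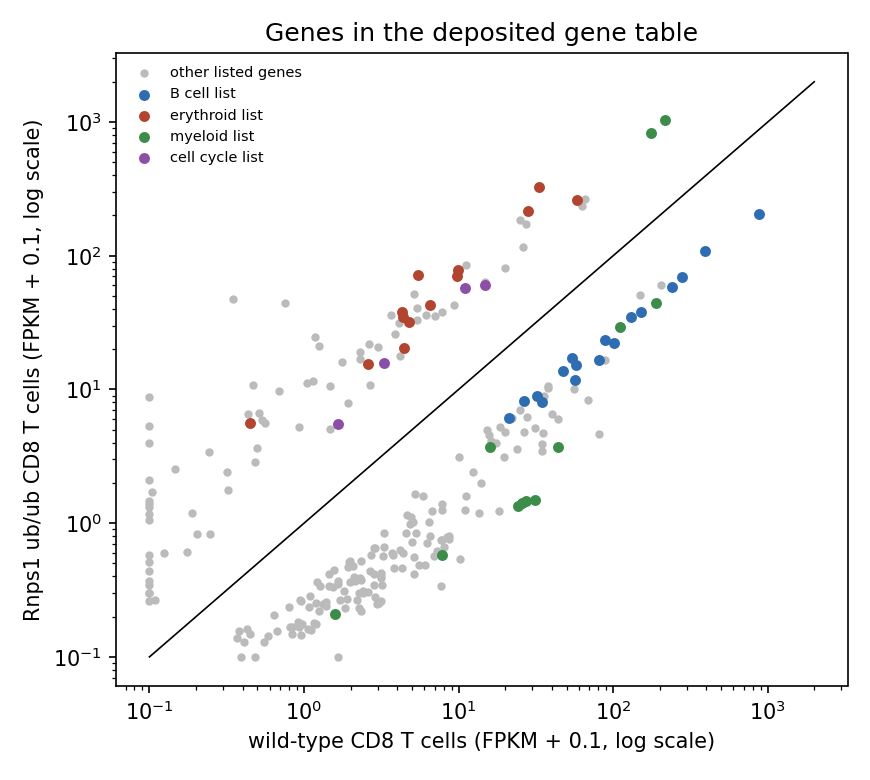
Expression of the 267 listed genes in wild-type (horizontal axis) and ub/ub (vertical axis) CD8 T cells, in FPKM plus 0.1 on log scales; each point is a gene, colours mark fixed gene lists, and the line marks equal values. All 12 erythroid and 4 cell cycle genes lie above the line and all 17 B cell genes below it.

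The functional terms of the authors followed the same gene groups. In the authors' deposited table of lower genes, 4 of 80 terms had a Benjamini value under 0.05. In the authors' deposited table these were infection with Staphylococcus aureus (Benjamini value of 0.0099; C1q and MHC class II genes), protein digestion and absorption (0.0156; carboxypeptidase and elastase genes), fat digestion and absorption (0.0232; lipase genes) and presentation of exogenous peptide on MHC class II (0.0475; Cd74, H2-Eb1, H2-Aa and H2-Ab1). In the authors' deposited table of higher genes, 0 of 10 terms passed, the lowest Benjamini value being 0.591, and 4 had an unadjusted P under 0.05, among them sequence-specific DNA binding, with Nfe2, Tal1 and Gata1, and innate immune response. A sheet name ends in DAV, which may stand for the DAVID tool.

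The isoform tables asked whether transcripts with a premature stop codon make up a different share of their gene in the mutant. In CD8 T cells the share was higher in the mutant for 20 of 33 listed isoforms and lower for 13 (two-sided exact binomial p = 0.296), so that the direction was not uneven beyond chance. The 33 isoforms belonged to 17 genes. A set of 8 isoforms passed a q-value of 0.05 of their own in the authors' deposited table, 4 of them higher and 4 lower. The share carried by the listed isoform of Kansl1l rose from 27.7 to 44.7%, of Gbp9, an interferon-inducible guanylate-binding protein gene, from 53.9 to 74.3%, of Gm28035 from 59.4 to 87.4% and of Gm45479 from 84.7 to 100%. It fell from 28.0 to 2.54% for Dbndd2, from 16.7 to 0.0267% for Gm38431 (q-value of 5.35e-25 in the authors' deposited table), from 18.8 to 5.95% for Slx1b, which encodes a structure-specific endonuclease subunit, and from 54.1 to 36.7% for Atp6v1g2. In HSCs 3 isoforms were listed, of Armcx5 (16.4 to 5.60%), Gm33378 (3.24 to 0.373%) and Gbp8 (3.69 to 2.84%), and none passed a q-value of 0.05 of its own in the authors' deposited table.

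The splicing tables asked which events differ between genotypes. In ub/ub CD8 T cells retained introns were mostly higher and exons were mostly used less than in wild type. Of 795 listed introns, 760 were higher and 35 were lower in the mutant (95.6% higher, 95% interval 93.9 to 96.9; adjusted exact binomial p = 5.94e-178). Of 274 listed exons, 226 were lower and 48 were higher (82.5% lower; adjusted exact binomial p = 1.73e-28). By the change in inclusion share 198 of the exons fell and 76 rose. Alternative 3' and 5' splice sites each had 21 events lower and 1 higher (adjusted exact binomial p = 1.1e-05). The 1113 events fell in 879 genes, and 710 of the introns lay within coding regions. Of the 1113 events 290 had a false discovery rate under 0.05 in the authors' deposited table, and the highest rate among all listed events was 0.306. In each of the other splicing tables below, the highest rate was 0.945 or more. By that rate most events listed there may be false calls, which limits what their directions show. The inclusion share moved in the same direction as the log2 change for 93.9% of events. Fisher's exact test on pooled reads gave an adjusted p under 0.05 for 801 events, 794 of them in the direction of the table. The events had been selected at P under 0.05 from the same libraries, so this count is not independent evidence.

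**Figure D2:**
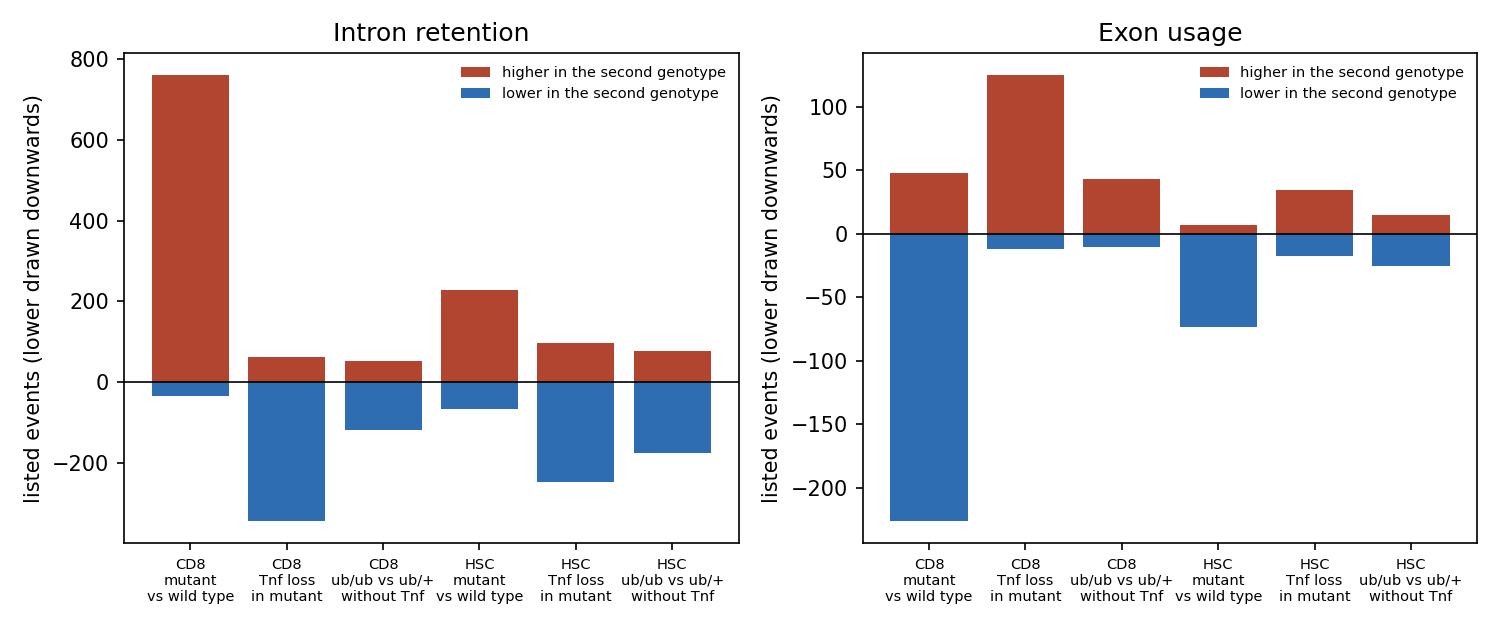
Number of listed splicing events that were higher (upwards, red) or lower (downwards, blue) in the second genotype, for retained introns (left) and exons (right) in the 6 comparisons. In ub/ub against wild-type CD8 T cells 760 introns were higher and 35 lower, and on loss of Tnf 62 were higher and 344 lower.

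Intron 3 of 6 of Ctrl, a chymotrypsin-like protease gene, on chromosome 8 (105932906 to 105932979, mm10) had the smallest false discovery rate among the named events of this table, 6.33e-10 in the authors' deposited table. It was retained in 2.53% of wild-type reads (interval 1.74 to 3.56) and 51.2% of mutant reads (38.7 to 64.2), on 96 mutant reads, while the expression of Ctrl itself went from 43.6 to 5.93 FPKM with those of the other acinar genes. Introns 5 and 6 of Nr1h3, a nuclear receptor gene of macrophages, went from 2.39 to 25.7% and from 5.59 to 35.5%, on 44 and 21 mutant reads. Retention rose by 5.03 percentage points in Abhd17a to 6.99% and in Nucb2 from 4.35 to 16.9%, and it fell in Ift140 from 5.62 to 0.746%. Exon use fell in Trim26, a ubiquitin ligase gene, from 59.4 to 31.7% (exon 6 of 10, chromosome 17, 36854284 to 36854301), and in Sptan1 from 10.5 to 3.07%. For exons of Fcgr2b and Dnase2a, which were lower in the authors' deposited table, the inclusion share moved the other way, from 57.5 to 58.1% and from 82.7 to 86.4%.

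Genes of splicing itself were among those with retained introns: 24 of the 81 splicing factor genes had a listed event, with 22 introns higher and 1 lower. Retention rose in Hnrnpa3 from 7.63 to 16.1% (intron 3 of 10), in Srpk1, which encodes a kinase of splicing factors, from 10.2 to 19.3%, and in Sf3a1, a component of U2 particles, from 6.61 to 12.7%. An intron of U2af2 (90.2 to 91.4%) and an exon of Son (1.09 to 2.68%) were higher by few points, and an intron of Hnrnpu had a higher log2 change in the authors' deposited table although its share was 90.8% in wild type and 88.7% in the mutant. Of the exon junction complex and RNA surveillance list, an intron of the RNA export gene Nxf1 rose from 20.5 to 33.7%, and exon 2 of Rnps1, in the 5' untranslated region, was at 18.6 and 19.9% with a false discovery rate of 0.21 in the authors' deposited table. Of T cell identity genes, Lat, the adaptor of T cell receptor signalling, had introns 4 and 5 of 11 rise from 6.50 to 10.7% and from 10.2 to 18.4%. Exon 4 of Ptprc, one of the variable exons of CD45, fell from 21.9 to 11.5%; B cells use these exons more than T cells do, and B cell genes were lower in the same libraries, so the fall may follow the amount of B cell RNA. Intron 1 of Cd8a went from 14.3 to 22.5% at a false discovery rate of 0.130 in the authors' deposited table, and an exon of Skap1 from 92.6 to 90.8% at 0.213. Of the p53 and apoptosis list, introns 4 and 7 of Trp53 went from 8.68 to 14.9% and from 8.03 to 14.5%, and introns 1 and 5 of Atr from 4.29 to 4.19% and from 30.0 to 42.4%, none past 0.05. Neither the splicing factor list (adjusted p = 0.711) nor the p53 list (adjusted p = 1) nor the T cell identity list (adjusted p = 0.891) was over-represented against genes listed only in other splicing tables by Fisher's exact test.

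In ub/ub HSCs the same directions were seen. Of 296 introns 229 were higher and 67 lower (77.4% higher, 95% interval 72.2 to 82.0; adjusted exact binomial p = 2.77e-21), and of 80 exons 73 were lower and 7 higher (adjusted p = 1.16e-14). Alternative 3' splice sites were lower in 11 of 12 events and alternative 5' sites in all 8 (both adjusted exact binomial p = 0.00781). Introns of Fam53a (0.475 to 1.46%), Armt1 (3.90 to 5.56%), Atxn2l (77.9 to 81.0%) and Hdc, the histidine decarboxylase gene (0.588 to 0.865%), were higher. Retention of an intron of Rsrp1 fell from 61.3 to 50.3%, use of an exon of the same gene from 2.67 to 1.06%, and an alternative 3' splice site of March7 from 92.4 to 75.6%. An intron of Eif4a1 was lower by the log2 change of -0.70 in the authors' deposited table, although its share was 0.295% in wild type and 0.341% in the mutant. Of the stem cell list, 2 exons of Erg were lower (51.8 to 47.8% and 84.8 to 84.1%), and of the splicing factors, introns of Srpk1 (1.34 to 2.67%), Hnrnpl (6.61 to 7.90%) and Tial1 (55.7 to 59.6%) were higher, while an intron of Zranb2 (1.82 to 1.24%) and exons of Luc7l3 (6.93 to 4.30%) and Ptbp3 (21.5 to 18.3%) were lower, none past a false discovery rate of 0.05. Only 10 of the 396 events had a false discovery rate under 0.05 in the authors' deposited table, 6 introns among them higher and 2 lower.

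The next comparison asked what the loss of Tnf does in ub/ub CD8 T cells, and the directions were the opposite of those between mutant and wild type. Without Tnf 344 of 406 introns were lower and 62 higher (84.7% lower; adjusted exact binomial p = 7.38e-48), and 125 of 137 exons were higher and 12 lower (91.2% higher; adjusted p = 1.41e-24), although by the change in inclusion share 65.0% of the exons were higher. All 12 alternative 3' splice sites were higher (adjusted exact binomial p = 0.000651), and 3 of 4 alternative 5' sites were (adjusted p = 0.625). Exon 4 of Atf2, a stress-activated transcription factor gene, rose in use from 9.29 to 18.9% without Tnf, exon 10 of the adaptor gene Sh3pxd2a from 82.8 to 94.0%, and exon 6 of Senp6, a SUMO protease gene, from 35.2 to 47.4%. Retention fell in Tpp1, a lysosomal protease gene, from 9.90 to 2.62%, in Hax1 from 6.69 to 1.55%, and in Renbp from 6.85 to 0.905%. An intron of 5830411N06Rik was at 6.12% with Tnf and had 0 retained reads without it, on 81 reads, which allows up to 4.45%. An intron of Rdm1 (5.96 to 7.79%) was higher. For Hsd17b12 (exon, 92.8 to 90.9%) and Sort1 (intron, 0 to 1.74%) the share moved against the log2 change in the authors' deposited table. Of the splicing factor list, 4 introns were lower and 2 higher, and 5 exons were higher and 1 lower, none past a false discovery rate of 0.05. Introns of Snrpb (6.46 to 3.75%), Srsf1 (27.7 to 21.5%) and Snrnp70 (3.27 to 2.37%) were among the lower and exons of Mbnl1 (2.73 to 3.99%) and Celf2 (64.9 to 70.3%) among the higher, as was an exon of Rbm39 although its share fell by 0.450 percentage points from 3.45%. The 2 higher introns, of Clk1 (60.5 to 62.5%) and of Clk4, whose share fell from 36.2 to 28.9%, and the lower exon, of Hnrnpa1 (6.20 to 6.16%), were named after their values were seen. Of the 559 events 53 passed that rate in the authors' deposited table.

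In ub/ub HSCs the loss of Tnf was measured on 2 samples with Tnf and 1 without. Of 343 introns 247 were lower and 96 higher (72.0% lower; adjusted exact binomial p = 7.12e-16), and of 52 exons 35 were higher and 17 lower (adjusted p = 0.0351). Retention in Rpl23, a ribosomal protein gene, fell from 80.0 to 57.6%, in Brd8 from 5.28 to 1.80% and in Ncaph2, a condensin gene, from 2.51 to 0.684%. An intron of Trappc11 was retained at 3.61% with Tnf and had 0 retained reads without Tnf, which allows up to 1.95%, and an intron of Rabep1 also had 0 retained reads without Tnf, which allows up to 2.98%. Retention rose in H3f3b, a histone H3.3 gene, from 3.41 to 5.81% and in Jarid2 from 3.21 to 4.08%. For Npr2 it went from 0 to 37.1% on 21 and 24 reads, and an exon of Wiz was used at 63.8 and 67.6%. By the change in inclusion share 53.8% of the exons were higher, which did not differ from an even split. Only 13 of the 402 events had a false discovery rate under 0.05 in the authors' deposited table, and among these introns 6 were higher and 6 lower, so the uneven split rests on events past P of 0.05 alone. The HSC libraries without Tnf carry names of another series than those with Tnf, so library set and Tnf genotype cannot be told apart.

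The last comparison asked how homozygous and heterozygous carriers differ once Tnf is gone. The sample labels give +/ub for the first group, while the design text of the series names Rnps1 wild-type mice without Tnf; the labels were followed, and if they are wrong the comparison is with wild type. In CD8 T cells 118 of 169 introns were lower in the homozygote and 51 higher (adjusted exact binomial p = 1.08e-06), and 43 of 53 exons were higher (adjusted p = 1.11e-05). Among events whose share changed by at least 10 percentage points 46.2% of the introns and 70% of the exons were higher, and neither split passed the exact binomial test. Of 229 events 3 passed a false discovery rate of 0.05 in the authors' deposited table: introns of H2afz (5.43 to 3.45%) and Colgalt1 (6.10 to 2.72%) were lower, and an intron of Atxn2l had a higher log2 change with shares of 63.6 and 57.3%. By the change in inclusion share 56.6% of the exons were higher, which did not differ from an even split. Exon 3 of Rnps1 was at 26.6% in heterozygotes and 22.9% in homozygotes, and did not pass a false discovery rate of 0.05 in the authors' deposited table. In HSCs 177 of 253 introns were lower and 76 higher (adjusted exact binomial p = 7.48e-10), and the 40 exons were not split unevenly (15 higher, 25 lower; adjusted p = 0.308). Of 301 events 2 passed it in the authors' deposited table: an intron of Traf7, which encodes a TNF receptor associated factor, had 0 retained reads in heterozygotes, which allows up to 0.485%, and a share between 0.700 and 4.09% (95% interval) in the homozygote, and exon 2 of Gvin1 was used at 31.0 and 22.1%. The single homozygous HSC sample gives no spread between replicates, and among HSC introns whose share changed by at least 10 percentage points 53.6% were higher in the homozygote.

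Events listed in a pair of tables were compared for direction. Mutant CD8 T cells and mutant HSCs shared 90 events, and 84 of them had the same direction (93.3%). Because each table is split unevenly by itself, much agreement or opposition between tables can follow from these splits alone, so directions were also compared within a type. Of the 67 shared introns 94.0% had the same direction, against 75.0% from the splits of the tables (adjusted Fisher's exact p = 0.00402), and of the 19 exons 89.5% against 76.8% (adjusted p = 0.316). Mutant against wild type and Tnf loss in CD8 T cells shared 154 events, of which 141 had opposite directions (91.6%). Of the shared introns 90.2% were opposite, against 81.7% from the splits, and a link between the directions in both tables was not shown (adjusted Fisher's exact p = 0.165), while of the 28 exons 96.4% were opposite against 76.8% (adjusted p = 0.00537). These tables use separate libraries. At the 123 shared introns the median retained share was 7.90% in wild type and 14.6% in ub/ub cells of the first set, and 8.29% with Tnf and 4.93% without Tnf in ub/ub cells of the second set. The ub/ub cells of the second set were below those of the first at 106 of the 123 introns and below wild type at 67. At the 28 shared exons the median share was 68.9% in wild type and 57.1% in ub/ub cells of the first set. In the second set it was 61.4% with Tnf and 62.8% without Tnf, so the opposite directions there rest on log2 changes more than on shares. Mutant against wild type in CD8 T cells and Tnf loss in HSCs had opposite directions at 58 of 73 shared events; of the 72 introns among them 79.2% were opposite, against 70.1% from the splits (adjusted Fisher's exact p = 0.136). For the 54 events shared by mutant against wild type and Tnf loss in HSCs, 52 had opposite directions, but both tables use the ub/ub group with Tnf. A simulation without differences, in which that group has the same values in both tables, left 0.243% with the same direction. The deposited shares of that group were equal in 0 of the 54 events, so the simulated value is only a guide. Tnf loss and zygosity also have a group in common. Their directions were the same at 83 of 87 shared events in CD8 T cells (simulated 99.9%) and 118 of 119 in HSCs (simulated 100%). Tnf loss in CD8 T cells and in HSCs shared 41 events, 23 in the same direction (56.1%). Of their 38 introns 57.9% had the same direction, against 65.3% from the splits. Mutant HSCs and Tnf loss in CD8 T cells were opposite at 64.7% of 34 introns, against 69.0%. For zygosity all 11 introns shared by both cell types had the same direction, against 57.9%. At a false discovery rate under 0.05 in each table, mutant against wild type and Tnf loss in CD8 T cells still shared 9 events, all with opposite directions, and mutant CD8 T cells and HSCs shared none.

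**Figure D3:**
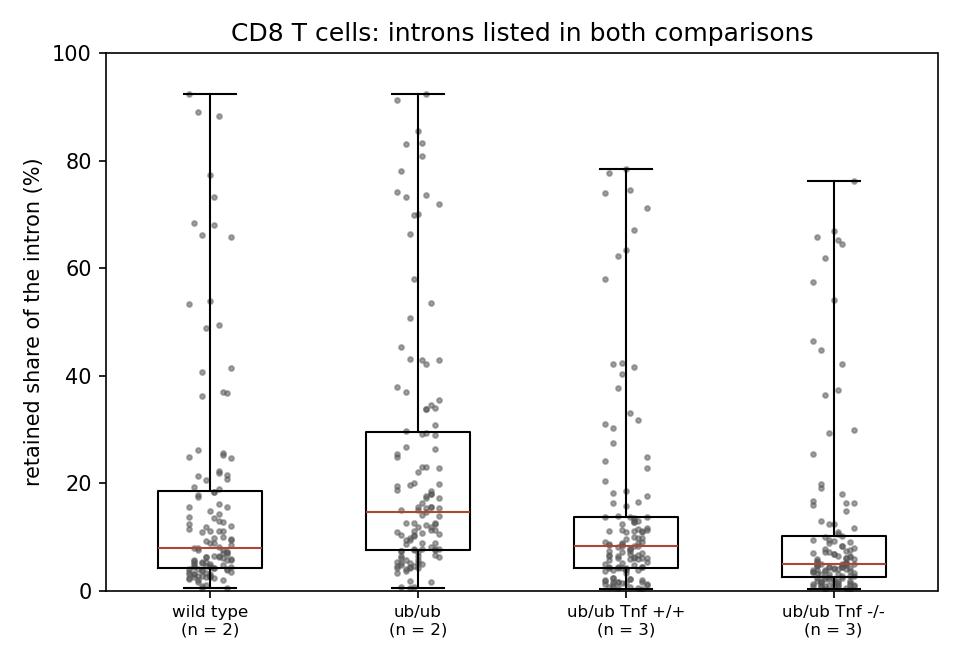
Retained share (percent of reads) of the 123 introns listed both for ub/ub against wild type and for Tnf loss in CD8 T cells; points are introns, red lines medians, boxes quartiles, whiskers the lowest and highest value, and n the samples pooled in a group. Medians are 7.90% in wild type, 14.6% in ub/ub cells of the first set, and 8.29% and 4.93% in ub/ub cells with and without Tnf of the second set.

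The types of events did not differ between the CD8 T cell tables (introns were 71.4% of events for mutant against wild type and 72.6% for Tnf loss; adjusted Fisher's exact p = 0.969). In HSCs introns made up 85.3% of events on Tnf loss against 74.7% for mutant and wild type (adjusted Fisher's exact p = 0.00308), and exons 12.9% against 20.2% (adjusted p = 0.0299). Introns were 84.1% of the HSC events of the zygosity comparison (adjusted Fisher's exact p = 0.0293). None of these differences held among events at a false discovery rate under 0.05.

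The series title names TNF receptor signalling, and 8 genes of that list had an event in mutant CD8 T cells. Introns of Map3k14, which encodes the kinase NIK, (4.38 to 6.16%), Rnf31 (11.2 to 18.9%), Ikbkb (62.5 to 81.9%), Cyld (10.3 to 15.6%) and Traf1 (31.3 to 40.9%) were higher, and exons of Mapk14, Nfkb1 and Cflar were lower by log2 changes of -0.38, -0.37 and -0.30 in the authors' deposited table, although the shares of Mapk14 (81.6 to 83.2%) and Cflar (87.2 to 87.8%) rose and that of Nfkb1 fell from 82.6 to 81.9%. Of these events only that of Map3k14 passed a false discovery rate of 0.05, at 0.0431 in the authors' deposited table, and the list was not over-represented in this table (8 of 879 genes; adjusted Fisher's exact p = 0.241). Other tables held Ikbkb in mutant HSCs (2.56 to 3.26%), Atf2 and Mapk14 on Tnf loss in CD8 T cells, Cyld on Tnf loss in HSCs (2.92 to 1.05%) and Atf2 for zygosity in CD8 T cells (17.7 to 18.9%). Genes with both a listed splicing event and listed expression numbered 8 in mutant CD8 T cells, with 12 events: Ctrl, Nr1h3, Cd68, Plbd1, Cd74, 5031439G07Rik, Cr2 and Lcn2. Of these 7 were lower and 1, Lcn2, was higher, a split that did not differ from that of the other listed genes (Fisher's exact p = 0.273).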

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

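All tests of explanations in this part were chosen after the results had been seen, except the comparison of intron lengths.

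Genes of other cell types differed between the ub/ub and wild-type CD8 T cell libraries, and in opposite directions. A lower share of CD8 T cells in 1 genotype, with the same mix of other cells, would move all other types alike. The tables argue against that case only, since all 12 listed erythroid genes were higher in the mutant and all 17 listed B cell genes were lower. A lower share of CD8 T cells together with another mix of other cells stays open, as it sets no common direction. More B cell RNA in the wild-type libraries may account for the B cell part, as the log2 changes of the 17 genes had a standard deviation of 0.187 around a median of -1.92, with Cd74 at 872 FPKM in wild type and 207 FPKM in the mutant. It does not account for 5 of 8 listed immunoglobulin variable genes, which were 7.49- to 10.2-fold higher in the mutant and stay unexplained. More RNA of splenic macrophages stays open in the same way (16 of 19 genes listed, all lower, standard deviation 0.824; Hmox1 at 43.8 and 3.61 FPKM; 8 genes of that list also stand in the myeloid list), as does acinar RNA of the pancreas next to the spleen (12 of 22 genes listed, all lower; Ctrb1 at 88.9 and 16.6 FPKM). No sort gate that would remove these cells is given in the sources used here, and whether the Rnps1 genotype itself changes the make-up of the spleen was not tested.

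Retained introns lay higher in ub/ub than in wild-type CD8 T cells and lower on Tnf loss, and a pattern this uniform raises the question of unspliced RNA in the libraries. Unspliced RNA alone would leave exon junctions unchanged. At a false discovery rate under 0.05, 16 exon events had a junction share that fell by 10 percentage points or more in the mutant. Rises of that size numbered 0. These exon events argue against unspliced RNA as the only difference between the libraries. They do not test the introns, for which unspliced RNA stays open. Of these 16 events 3, in the B cell gene Cr2 and in Ptprc, may follow the amount of B cell RNA, and 13 in 10 genes outside the lists of other cell types and the gene table are left, 4 of them in Macf1, named after its values were seen; whether those genes are spliced otherwise in other cell types was not examined. A difference in intron reads between sets of libraries could account for part of the pattern: at the 123 introns listed in both comparisons, which were selected by both, ub/ub libraries with Tnf of the first and the second set differed by a median of 5.62 percentage points, against 4.81 between mutant and wild type. Intron length cannot be told apart from chance between mutant and wild type (medians of 347.5 bp for higher and 175 bp for lower introns, permutation p = 0.0916); 35 introns were lower, and what a test on that number can detect was not examined. On Tnf loss higher introns were longer as well (413.5 against 228 bp, permutation p = 0.00333). A change of splicing by the Rnps1 and Tnf genotypes stays open and untested against these library sets.

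The HSC table of Tnf loss ended in 157 entries, all introns, that were equal in every cell to entries of the CD8 T cell table and were used in no comparison. They stood together in 1 run at the end of the table, which is consistent with a block carried from 1 table to the other. No biological explanation was tested.

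Shares of higher events also differed between the tables of the 2 cell types under the same contrast. For mutant against wild type, 290 of 1113 CD8 T cell events and 10 of 396 HSC events had a false discovery rate under 0.05. On Tnf loss these were 53 of 559 and 13 of 402. False calls can pull a share towards an even split, and events are not replicates. The tests below therefore compare lists and do not show a difference between the cells. Introns were higher in 95.6% of mutant CD8 T cell events and 77.4% of mutant HSC events (Fisher's exact test of the difference, adjusted p = 5.72e-17). On Tnf loss introns were higher in 15.3% of CD8 T cell events and 28.0% of HSC events (adjusted exact p = 5.69e-05). Exons were higher on Tnf loss in 91.2 and 67.3% (adjusted exact p = 0.000235). Exons were higher in homozygotes without Tnf in 81.1% of CD8 T cell events and 37.5% of HSC events (adjusted exact p = 5.69e-05). By the change in inclusion share the 2 exon differences were smaller and no longer passed, at 65.0 and 53.8% on Tnf loss (adjusted exact p = 0.272) and at 56.6 and 32.5% in homozygotes without Tnf (adjusted exact p = 0.0701), while both intron differences remained (adjusted exact p = 3.45e-14 and 6.03e-05).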

How the results depend on the processing

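The settings that took direction from the inclusion share, kept the repeated entries, left out marker genes or genes of the gene table, or counted repeated terms were chosen after the results had been seen; the others were planned. Over 162 values for 73 results under other settings, 111 kept their direction and their side of the threshold, or stayed within 1.5 times a count. The split of listed genes and of list members and the directions of introns and exons in mutant CD8 T cells held under every setting run. For genes, a minimum log2 change of 1 removed none, and a pseudocount of 1 FPKM cannot change a direction. These settings could not alter the split of genes, so the values kept under them were fixed in advance. Stricter thresholds leave fewer events by construction; for other changes the cause was not tested. No paired analysis was possible because the replicate numbers only follow the order of the samples and pair none. Leaving out single replicates and models on reads per library were not run, and no model across groups was fitted here. No gene reached a q-value of 0.01 (lowest 0.0142), so that threshold gave no value for genes, lists or genes in both tables. The 198 genes at the lowest q-value also share the lowest listed p-value. It may thus be a floor of the p-values and not a measure of support for a gene.

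At a false discovery rate under 0.05 the events numbered 290 and 10 for mutant against wild type in CD8 T cells and HSCs, 53 and 13 for Tnf loss, and 3 and 2 for homozygous against heterozygous. With a change in inclusion share of at least 10 percentage points they numbered 241 and 41, 74 and 47, and 37 and 50. At a Benjamini value under 0.01, 1 term of lower genes was left, and at an isoform fraction change of at least 20 points, 3 CD8 T cell isoforms, all 3 at their own q-value under 0.05, and no HSC isoform.

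At the false discovery rate the directions no longer passed their test for mutant HSCs (75% of introns and 0% of exons higher), exons on Tnf loss in CD8 T cells (71.4% higher), introns and exons on Tnf loss in HSCs (50% and 100% higher) and introns for zygosity in CD8 T cells (33.3% higher). Introns for zygosity in HSCs reversed to 100% higher, on 1 intron. With a change of at least 10 points they no longer passed for introns and exons on Tnf loss in HSCs (38.2% and 70% higher) and for zygosity in CD8 T cells (46.2% and 70% higher), and introns for zygosity in HSCs reversed to 53.6% higher. By the change in inclusion share 53.8% of exons were higher on Tnf loss in HSCs and 56.6% for zygosity in CD8 T cells, no longer past the test, and 32.5% for zygosity in HSCs, not past it as before.

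The larger part of introns and smaller part of exons among HSC events had adjusted p = 1 by Fisher's exact test at the false discovery rate on Tnf loss, and also for zygosity, where the difference reversed; with 1 event per gene and type the exon value on Tnf loss was 0.0578. Events at that rate in both tables of a pair numbered 9 for mutant against wild type and Tnf loss in CD8 T cells. They numbered 1 for mutant CD8 T cells with Tnf loss in HSCs, for mutant HSCs with Tnf loss in CD8 T cells and with Tnf loss in HSCs, each reversed to 100% in the same direction. They also numbered 1 for mutant HSCs with zygosity in CD8 T cells, and for Tnf loss with zygosity in CD8 T cells (100% in the same direction, no longer past the test). The other pairs shared no event at that rate. With the repeated entries kept, Tnf loss in HSCs shared 114 events with mutant CD8 T cells, 179 with Tnf loss in CD8 T cells (93.3% in the same direction) and 52 with zygosity in CD8 T cells (84.6%), the last 2 shares now past the test. Without them the last 2 pairs had 56.1% of 41 and 73.7% of 19 shared events in the same direction. The repeated entries equal those for Tnf loss in CD8 T cells, so their agreement with these is by construction. Genes of the TNF list at the false discovery rate numbered 1 in mutant CD8 T cells and 1 on Tnf loss in CD8 T cells, and none elsewhere. The binomial test of shared directions does not allow for the uneven split of each table, so passing it shows no link between tables. Depth limits shares with 0 retained reads, which allow up to 4.45% for the intron of 5830411N06Rik on 81 reads. The ub/ub HSC group without Tnf rests on 1 library and gives no spread.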

Other observations

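The reading frame test and its prediction were set before its result was seen; the test of intron rank, the comparison with other exons, the added lists and the replicate checks were chosen after results had been seen.

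Genes of interferon response carried retained introns in mutant CD8 T cells. Of 68 genes on that list, 10 had a listed event, with 11 introns higher and 1 lower. Of all listed introns in mutant CD8 T cells 95.6% were higher, so the direction is not particular to this list. Fisher's exact test against genes listed only in other splicing tables gave an adjusted p of 0.0124. That adjustment ran over the 6 tables and not over the 16 lists, so over-representation of the list is not claimed. The following genes lie outside the rule for named genes and were chosen after their values were seen. Retention rose in Parp14 from 16.9 to 32.1%, in Irf7, a master regulator of interferon genes, from 8.49 to 17.2% (intron 6 of 9), in Phf11d from 10.8 to 50.9% on 43 mutant reads, in Psmb9, an immunoproteasome subunit gene, from 74.5 to 88.4%, and in Tap1, a peptide transporter gene, by 6.84 percentage points, each at a false discovery rate under 0.05 in the authors' deposited table. The Irf7 intron was also listed as higher in mutant HSCs (4.57 to 8.24%) and lower on Tnf loss in CD8 T cells (24.8 to 16.3%), neither past that rate. Cell cycle genes showed the same direction in mutant CD8 T cells, with 5 introns higher and none lower, among them intron 1 of the cyclin gene Ccnd2 (5.05 to 12.5%), and 5 introns of cell cycle genes were lower on Tnf loss in HSCs, but the list was not over-represented in either table (adjusted Fisher's exact p = 0.8 and 0.316). Of B cell genes, 6 exons in Cr2, Cd72 and Cd74 were lower in mutant CD8 T cells, among them exon 6 of Cr2 (59.5 to 44.1%). Other lists had few events in mutant CD8 T cells: 3 in cytotoxic effector genes, 5 in naive and memory genes, 2 in T cell receptor activation and checkpoint genes, 2 in myeloid genes, 1 in CD4 and NK genes, 1 in stem and progenitor genes, and 0 in erythroid and in megakaryocyte and platelet genes.

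Granulocyte genes were higher in the mutant CD8 T cell libraries. Of a neutrophil list written after the table had been seen, 5 of 15 genes were listed, all higher, with a median log2 change of 2.26; S100a8 stood at 217 and 1039 FPKM, S100a9 at 177 and 834 FPKM and the lipocalin gene Lcn2 at 25.9 and 115 FPKM, and 10 genes of that list also stand in the myeloid list. Of a list for basophils and mast cells, 3 of 7 genes were listed, all higher, with a median of 3.14: the protease genes Mcpt8 (3.53 to 36.0 FPKM) and Prss34 (3.80 to 26.0 FPKM) and the IgE receptor gene Fcer1a (0.399 to 3.53 FPKM).

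Exons are called used less or used more here by the sign of the log2 change and not by the inclusion share. Those used less in mutant CD8 T cells may be those whose loss keeps the reading frame. Of 215 coding exons used less, 113 had a length that is a multiple of 3, or 52.6% (95% interval 45.7 to 59.4; exact binomial p = 7.16e-09 against the share of 1 in 3). Among other internal coding exons 40.2% of 11447 did, so 1 in 3 is too low a reference. The difference remained in Fisher's exact test against these exons (odds ratio 1.65, p = 0.00033). They were not limited to exons whose use varies, so the test cannot tell an effect of genotype from a trait of such exons. Of the exons used more, 13 of 28 did (46.4%, 95% interval 27.5 to 66.1), so a tie to exons used less alone is not shown. Transcripts that lose the frame can be removed by RNA surveillance, so these reads cannot separate the splicing step from the stability of its products.

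Short introns of a transcript may be those retained. The 732 introns with a rank that were higher in mutant CD8 T cells had a median length rank of 33.3% among the introns of their own transcript, against 50% for permutation draws of 1 intron from the same transcripts (p = 1e-05, the smallest that the draws can give), and 144 were the shortest of their transcript, against 81.9 drawn. The 34 ranked introns that were lower had a median rank of 15.5%, so the rank does not separate higher from lower introns in that direction.

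Isoform fractions show how many libraries a mean was taken over. In units of 0.01%, and to within 0.002 of a unit, all 33 wild-type fractions in CD8 T cells were whole when multiplied by 2, and all 32 mutant fractions above 0 when multiplied by 3 but only 11 by 2, although the header names 2 cultures per genotype. The 3 mutant HSC fractions were whole when multiplied by 3, with 2 samples listed. At 54 events listed both for mutant HSCs and for Tnf loss in HSCs, the share of the ub/ub group with Tnf was equal in 0, with a median difference of 0.393 percentage points between the tables. Exclusion reads of replicate columns differed beyond counting error in all 19 pairs of columns, with chi-square values of 3.33 to 38.5 per degree of freedom.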
